A study of Mus musculus with 9 samples.

How the data were processed

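Messenger RNA of the mouse nucleus accumbens was sequenced after daily intraperitoneal injection of saline (10 ml/kg) or cocaine (10 or 20 mg/kg, per the labels, which do not tie a dose to a sample) for 7 days. The labels give 24 h between the last injection and harvest, or 8 days for withdrawal. Per the labels' protocols, RNA of 8 mice was pooled per group, poly(A) RNA was copied with random primers, inserts were about 200 bp, and each library was run in 3 lanes with 37 cycles from each end. Groups and lane numbers were taken from the sample titles. The values are RPKM made by the authors, given per lane and as 1 composite per library, with a total for each lane and library, per the file headers. Bowtie 0.12.7 and genome build mm9 are named in the submitters' processing notes; the counter and the annotation were not given in the sources used here. The composites matched depth-weighted means of the 3 lanes to within a relative gap of 6.9e-14. Multiplied by the lane total and a gene length, the values came out as whole multiples of 1/37 of a read within a relative tolerance of 2e-13, so reads are not whole and count tests were not run. The smallest length that gave this was taken as the gene model length, for all 21423 genes. Where all reads lie whole in a gene this length is short by a factor of 37, so it was multiplied by 37 for the 114 genes (16 tested) where only the product came within 1.5 times of the reference length, or where it was under 37 bp, a step added after results had been seen. Lengths had a median ratio of 1.06 to lengths in the reference, which is another build, so no coordinates are given. GC content was taken from the reference for 98.0% of the 14051 tested genes.

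Values were transformed to log2(RPKM + 0.5), which understates changes of low genes, and averaged over the 3 lanes of a library. Genes with a mean of at least 1 RPKM over the 9 lanes were tested. A gene was called when the libraries differed by at least 1.5 times and no lane of one overlapped the lanes of the other. Since lanes are technical runs, n was 1 library per group and no p-value about the treatment was computed. Lane totals from 5546362 to 12026754 make 1 read in a gene of 2 kb worth 0.0416 to 0.0902 RPKM, and the median SD of log2 values between lanes was 0.114 to 0.130, with lane correlations of 0.976 to 0.985. Lanes without any difference between libraries were simulated 100 times from each gene's mean and its SD between lanes, to give the calls, overlaps and correlations that arise by chance. The median of each of 32 gene lists was set against 10000 random lists of the same size matched on mean expression in 20 bins, and as an alternative against lists matched in 10 bins of gene length with 5 bins of expression in each. The lists held immediate-early, glucocorticoid-responsive, medium spiny neuron, neuropeptide, peptide processing, glutamate receptor, GABA, synaptic vesicle, ion channel, actin, axon guidance, oxidative phosphorylation, ribosomal protein, proteasome, chaperone, chromatin, circadian clock, myelin, oligodendrocyte precursor, astrocyte, microglia, interferon-responsive, endothelial, meningeal, choroid plexus, cortical, septal and hypothalamic, interneuron, dorsolateral striatum, ventral striatum and erythrocyte genes, and nuclear non-coding RNAs with small nucleolar RNA hosts.

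The groups, tests, lists, rule for named genes and all alternatives except those said to be added later were fixed before the data were examined. Named genes were, per comparison, the 8 largest called changes in each direction at a mean of at least 3 RPKM over the lanes compared, the 4 members with the largest difference, called or not, of each list with a call, and Fos, Fosb, Arc, Egr1, Bdnf, Drd1a, Drd2, Pdyn, Penk, Tac1, Ppp1r1b, Cartpt, Kalrn and Pam. The part on list members was first applied to called members alone and was set to this fixed wording after values had been seen. Not every gene so chosen or counted is named; Rarres2, Folr1 and the genes of the closing observations lie outside the rule. Near-identical copies, predicted genes and very short models are called uncertain. As an alternative, limma 3.58.1 in R 4.3.3 with a mean-variance trend and robust fitting tested all 9 lanes at an adjusted p of 0.05 (Benjamini-Hochberg); it compares these libraries, not the treatments. Other alternatives were the pseudocount (0.1 and 1), the filter (5 RPKM or none), the size limit (a difference of 25%, and of 2 times), no condition on the lanes, centring on the median, scaling to the 75th percentile, the composite values, a lane-number block and leaving out each lane. Centring within 20 bins of gene length or of GC content and leaving out models under 200 bp were added after seeing the data. On simulated data for cocaine against saline with 14051 genes, the size rule recovered 44% of 50 genes changed 1.5 times, 92% at 2 times, 96% at 3 times and 94% at 4 times, and called 118 of 13851 unchanged genes; limma recovered 54%, 70%, 76% and 82% and called 5. Of 200 simulated lists of 25 unchanged genes 5% lay outside the middle 95%, and all were found when shifted by 0.3. Both these lists and the lists they were set against were drawn at random, so the 5% was fixed by the draw. It is no check on real lists, whose genes may move together. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.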

Results

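Messenger RNA was measured by sequencing in the nucleus accumbens, a part of the ventral striatum that takes part in reward and holds mostly medium spiny neurons, of adult male C57BL/6 mice. The mice were injected daily with saline or cocaine for 7 days. The saline and cocaine groups were killed 24 h after the last injection, and the withdrawal group was kept for 8 days without cocaine. RNA of 8 mice was pooled per group, 1 library was made from each pool, and each library was run in 3 lanes. The 9 samples were therefore 3 libraries with 3 technical lanes each, and no difference between treatments had a replicate check. Levels are means ± SD in RPKM over the 3 lanes of 1 library, and differences are on the log2(RPKM + 0.5) scale ± the standard error from the lanes, which covers sequencing only. Library totals were 26006605 for saline, 24219333 for cocaine and 19452882 for withdrawal, and lane totals ranged from 5546362 to 12026754. Of 21423 genes, 14051 with a mean of at least 1 RPKM were compared. A gene was called higher or lower where the libraries differed by at least 1.5 times and their lanes did not overlap. A gene list stood apart where its median lay outside the middle 95% of 10000 random lists matched on mean expression. Of 32 lists with members drawn at random, 1.6 would lie outside these bounds. Genes of a real list may move together, which this number does not cover.

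The first comparison asked which transcripts differed 24 h after repeated cocaine. Slc17a7, the vesicular glutamate transporter VGLUT1, fell from 18.3 ± 1.0 RPKM in the saline library to 5.54 ± 0.45 RPKM in the cocaine library (log2 difference -1.64 ± 0.078). Bmpr2, a receptor for bone morphogenetic proteins, rose from 3.82 ± 0.45 to 14.6 ± 0.45 RPKM (1.81 ± 0.092), and Tnr, an extracellular matrix protein of perineuronal nets, from 4.81 ± 0.55 to 17.1 ± 0.57 RPKM (1.73 ± 0.093). Grin2a, an NMDA receptor subunit, rose by 1.69 ± 0.095, Kcnq3, a potassium channel subunit of the M current, by 1.65 ± 0.14, and Sv2c, a synaptic vesicle protein, from 7.58 ± 0.45 to 22.3 ± 0.93 RPKM. In all, 411 genes were called higher and 338 lower, against a mean of 97.7 calls in simulated libraries without any change. Lanes did not overlap for 42.1% of genes, where chance gives 10%. The other genes among the 8 largest changes either way were Ttr, transthyretin, which the choroid plexus makes in large amounts (from 2.37 ± 0.94 to 7.51 ± 2.4 RPKM), Spata24 (-1.26 ± 0.28), Hmgn5 (-1.08 ± 0.35) and the predicted or very short models Snord49b, Mir1892, n-R5s185, Gm5136, Gm13625, Gm15738 and Gm13872, whose levels are uncertain.

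Neuropeptide and opioid system genes had a median of -0.42, below all the random lists, with 1 higher, 6 lower and 15 without a call. Pmch, a peptide precursor made mainly in the hypothalamus, fell by 1.73 ± 0.35, while Oprm1, the mu opioid receptor, rose from 0.908 ± 0.38 to 3.31 ± 0.59 RPKM (1.46 ± 0.25). Tac1, the substance P precursor, fell from 32.3 ± 1.2 to 19.0 ± 1.4 RPKM (-0.75 ± 0.066). Penk and Pdyn, the enkephalin and dynorphin precursors, had no call (-0.39 ± 0.054 and -0.29 ± 0.056). Peptide processing genes had a median of -0.14 and no call, and the amidating enzyme Pam differed by -0.11 ± 0.053. Dopamine and cAMP signalling genes of medium spiny neurons had a median of -0.17, within random lists matched on expression (percentile 36.2) and below those matched on length as well (percentile 1.8). Their single call was Ppp1r1b, which encodes DARPP-32 and fell from 655 ± 16 to 389 ± 15 RPKM (-0.75 ± 0.038). Drd1a and Drd2, the main dopamine receptor genes, differed by -0.12 ± 0.085 and -0.33 ± 0.12 without a call. Ventral striatum genes (median -0.16), where Cartpt fell from 53.8 ± 4.2 to 32.7 ± 1.8 RPKM (-0.71 ± 0.077) and Peg10 rose by 0.71 ± 0.017, lay within random lists. So did dorsolateral striatum genes (0.077, no call) and striatal interneuron genes (-0.068), where Nos1 rose by 0.61 ± 0.053. When centred by length, the list median was -0.19 for neuropeptide genes (1 higher and 3 lower), -0.092 for medium spiny neuron genes (2 higher and 1 lower) and -0.045 for ventral striatum genes (2 higher and 0 lower). With a lane dropped the call ended for Nos1 (0.58 without saline replicate 1).

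Immediate-early and activity-regulated genes had a median of -0.18 (percentile 0.49), with 0 higher, 5 lower and 26 without a call. Gadd45b fell by 0.89 ± 0.22, Arc from 15.6 ± 0.45 to 9.50 ± 0.96 RPKM (-0.69 ± 0.082) and Fos from 6.13 ± 1.2 to 3.56 ± 0.71 RPKM (-0.71 ± 0.21). Fosb (-0.29 ± 0.18) and Egr1 (-0.31 ± 0.10) had no call, and Bdnf, at 1.24 ± 0.53 RPKM in saline and 0.677 ± 0.19 RPKM in cocaine, stayed below the filter. The list also lay below random lists matched on length (percentile 1.4). Its place below random lists ended only when differences were centred by length, so the 2 length controls differ. Glucocorticoid-responsive genes had a median of -0.26 (percentile 0.65), although their 2 calls, Zbtb16 (0.67 ± 0.17) and Plin4 (0.60 ± 0.14), were higher. This list too lay below random lists matched on length (percentile 1.35), while length centring ended the outcome. Circadian clock genes lay within random lists, with a median of 0.040 that turned to -0.058 when centred by length, and Per2 rose by 0.59 ± 0.073. Length centring gave a median of -0.082 for immediate-early genes (0 higher and 2 lower) and -0.10 for glucocorticoid genes (1 higher and 0 lower). With 75th percentile scaling there were 0 higher and 3 lower among immediate-early genes and 2 higher and 0 lower among clock genes. GC centring left 0 higher and 3 lower among immediate-early genes. The call ended without 1 lane for Fos (-0.57 without saline replicate 3) and Zbtb16 (0.51 without cocaine replicate 1). Plin4 (0.47 without cocaine replicate 3, 0.57 without saline replicate 2) and Per2 (0.57 without cocaine replicate 1, 0.57 without cocaine replicate 3, 0.54 without saline replicate 2) lost the call when 1 lane was left out. Percentiles that changed a list's outcome without 1 lane were those of the glucocorticoid-responsive list (8.8 without cocaine replicate 3, 4.5 without saline replicate 2).

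Voltage-gated ion channel genes had a median of 0.26, above all the random lists, with 6 higher, 0 lower and 36 without a call. Cacna1e, a calcium channel subunit, rose from 9.02 ± 0.40 to 21.9 ± 0.80 RPKM (1.23 ± 0.046), and the calcium-activated potassium channel gene Kcnma1 rose by 1.01 ± 0.15. Glutamate receptor and postsynaptic density genes (median 0.19) had 2 higher, 0 lower and 41 without a call, with Grin2a among those higher. Axon guidance and adhesion genes (median 0.17) had 6 higher, 0 lower and 43 without a call, with Slit1 higher by 0.75 ± 0.063 and Epha6 by 0.73 ± 0.16. GABA system genes had a median of 0.11 and no call. Synaptic vesicle genes had a median of 0.021 and 2 higher, 1 lower and 25 without a call, Sv2c and Pclo (0.68 ± 0.034) being the higher ones. Chromatin regulator genes had one of 0.073, with Hdac4 (0.73 ± 0.11) among 4 higher. The glutamate, axon guidance, GABA, synaptic vesicle and chromatin lists lay above random lists matched on expression but within those matched on length as well, at percentiles 95.5, 69.3, 96.1, 64.4 and 40.5. Actin and dendritic spine genes lay within random lists (median -0.083), with Arhgap32 higher by 0.69 ± 0.039 and Kalrn, an exchange factor of spines, at 0.27 ± 0.045 without a call. After centring by length the median came to 0.052 for ion channel genes (6 higher and 0 lower), 0.081 for glutamate genes (2 higher and 0 lower), 0.13 for axon guidance genes (2 higher and 0 lower), -0.031 for synaptic vesicle genes (1 higher and 0 lower) and -0.020 for chromatin genes (1 higher and 0 lower). Under 75th percentile scaling the calls were 6 higher and 0 lower among glutamate genes, 10 higher and 0 lower among axon guidance genes and 2 higher and 0 lower among actin genes. GC centring left 4 higher and 0 lower among glutamate genes and 2 higher and 0 lower among actin genes.

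Cytosolic ribosomal protein genes had a median of -0.47 and nuclear-encoded oxidative phosphorylation genes one of -0.42, both below all the random lists, and every tested member of both lists (77 and 75 genes) had a negative difference under every scaling tried. Each list had 12 calls, among them Rps23, which fell from 128 ± 2.0 to 76.1 ± 4.7 RPKM (-0.75 ± 0.053), Rps28 (-0.77 ± 0.059), Ndufc1 (-0.90 ± 0.059) and Ndufb2 (-0.81 ± 0.15). When centred by length the medians were -0.24 and -0.20, and 0 and 2 calls were left. Ribosomal protein genes have many processed pseudogenes, so their levels are uncertain. Proteasome genes were also below all the random lists (median -0.35, no call), and chaperone genes lay within them (-0.17, no call). Centred by length, the median was -0.17 for proteasome genes. Calls under 75th percentile scaling were 0 higher and 4 lower among ribosomal protein genes and 0 higher and 5 lower among oxidative phosphorylation genes.

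Among markers of other cells, endothelial and mural genes had a median of 0.39, above all the random lists, with 6 higher, 0 lower and 19 without a call. Flt1, a VEGF receptor, rose from 2.95 ± 0.16 to 5.52 ± 0.39 RPKM (0.80 ± 0.067) and the angiopoietin receptor Tek by 0.74 ± 0.12. Oligodendrocyte precursor genes stood above random lists (median 0.34, percentile 99.9), with Tnr their call. Erythrocyte genes had a median of 0.40 over 7 genes, above all the random lists, with 1 higher, 1 lower and 5 without a call; Alas2, an enzyme of haem synthesis, was the higher one (0.60 ± 0.19). Septal and hypothalamic genes (median 0.083, percentile 97.8) had 2 higher, 0 lower and 21 without a call. Choroid plexus and ependymal genes had a median of -0.31 (percentile 0.40) over 9 genes, with 1 higher, 1 lower and 7 without a call. Length centring ended both outcomes, but both lists stayed outside random lists matched on length (percentile 97.6 and percentile 1.6). Of the choroid plexus and ependymal genes Ttr was the higher one and Ccdc153 the lower (-0.60 ± 0.26). Folr1, a choroid plexus gene of the list that stayed below the filter and was chosen after its values were seen, was at 0.158 ± 0.17 RPKM in saline, 0.805 ± 0.47 RPKM in cocaine and 0.0523 ± 0.091 RPKM in withdrawal. Myelin genes had a median of -0.019 (0.053 under 75th percentile scaling and 0.028 with the median difference set to 0), within random lists matched on expression and above those matched on length (percentile 98.7); after GC centring it was 0.073, above random lists. Within random lists lay cortical projection neuron genes (-0.021, or 0.044 under 75th percentile scaling and 0.026 with the median difference set to 0, Slc17a7 the single call), astrocyte genes (-0.15, no call), microglia and immune genes (-0.12, Cd68 lower by -0.59 ± 0.23), interferon-responsive genes (0.072, no call), meningeal genes (0.10, Fn1 higher by 1.22 ± 0.10) and nuclear non-coding RNAs with small nucleolar RNA hosts (-0.047, or 0.024 under 75th percentile scaling, no call). When centred by length, the list median was 0.19 for oligodendrocyte precursor genes (1 higher and 0 lower), 0.66 for erythrocyte genes (5 higher and 0 lower) and -0.16 for choroid plexus genes (1 higher and 0 lower). With 75th percentile scaling there were 1 higher and 0 lower among choroid plexus genes. GC centring left 1 higher and 0 lower among choroid plexus genes. A single lane decided the call of Alas2 (0.46 without cocaine replicate 1, 0.53 without saline replicate 2, 0.58 without saline replicate 3) and Ccdc153 (-0.39 without cocaine replicate 1, -0.47 without saline replicate 2). Without 1 of the lanes the call was lost for Cd68 (-0.37 without cocaine replicate 2, -0.57 without saline replicate 1, -0.57 without saline replicate 3). Also changed without 1 lane was the outcome (percentile) of the septal, preoptic and hypothalamic neuron list (97.1 without cocaine replicate 3, 96.1 without saline replicate 2) and choroid plexus and ependymal list (11.3 without cocaine replicate 1, 3.1 without cocaine replicate 2, 7.8 without saline replicate 1, 4.1 without saline replicate 2, 7.3 without saline replicate 3). The percentile crossed a bound without 1 lane for the oligodendrocyte and myelin list (99.0 without cocaine replicate 2, 98.8 without saline replicate 1, 97.7 without saline replicate 2).

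The differences between the cocaine and saline libraries followed gene length. Genes called higher had a median length of 4348 bp and genes called lower 1270 bp, against 3531 bp for all tested genes, and the Spearman correlation across genes of the difference with length was 0.464, where genes are not independent replicates. The split of 411 higher and 338 lower genes became 505 and 230 with the median difference set to 0, 535 and 204 with lanes scaled to the same 75th percentile, 477 and 98 when centred by length, and 496 and 237 when centred by GC content, with which the differences correlated at -0.0881. Of the 32 lists, 7 lay below and 10 above random lists. Centring by length turned the sign of the myelin (0.10), interneuron (0.091) and microglia (0.028) medians. Centring within bins of gene length, an alternative chosen after seeing the data, brought Cartpt (-0.39), Nos1 (0.31), Fos (-0.54), Plin4 (0.52), Per2 (0.52), Pclo (0.38), Arhgap32 (0.39), Rps23 (-0.55), Rps28 (-0.57), Flt1 (0.50), Ccdc153 (-0.32) and Cd68 (-0.31) under 1.5 times. It left Hmgn5 (-0.90), Snord49b (-1.83) and Gm5136 (-0.83) past 1.5 times, but with lanes that overlapped, which ended the call too. A pseudocount of 1 ended the calls of Plin4 (0.54), Per2 (0.55), Alas2 (0.51), Ccdc153 (-0.52) and Cd68 (-0.56). The composite value per library ended the calls of Alas2 (0.58), Ccdc153 (-0.55) and Cd68 (-0.54). GC centring, also chosen after seeing the data, ended the calls of Ccdc153 (-0.55) and Cd68 (-0.52). Scaling to the same 75th percentile ended the calls of Ccdc153 (-0.54) and Cd68 (-0.52). Setting the median difference to 0 ended the calls of Ccdc153 (-0.55) and Cd68 (-0.54). With 75th percentile scaling the list median was -0.11 for immediate-early genes, 0.19 for GABA genes, 0.092 for synaptic vesicle genes and 0.14 for chromatin genes. Likewise with 75th percentile scaling the list median was 0.15 for septal genes, -0.068 for peptide processing genes, -0.094 for chaperone genes and -0.076 for astrocyte genes. Length-centred medians were -0.035 for peptide processing genes, -0.058 for chaperone genes and -0.059 for astrocyte genes. With the median difference set to 0 the list median was 0.068 for synaptic vesicle genes, 0.12 for chromatin genes and 0.13 for septal genes. With GC centring the list median was 0.18 for GABA genes, 0.078 for synaptic vesicle genes, 0.13 for chromatin genes and 0.14 for septal genes. With length centring the list median was 0.20 for meningeal genes (percentile 98.0, outside the bounds). With a filter of 5 RPKM the list median was -0.34 for choroid plexus genes (percentile 5.0, within the bounds) and -0.011 for interferon genes. With no filter the list median was -0.017 for choroid plexus genes (percentile 36.3, within the bounds).

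**Figure D1:**
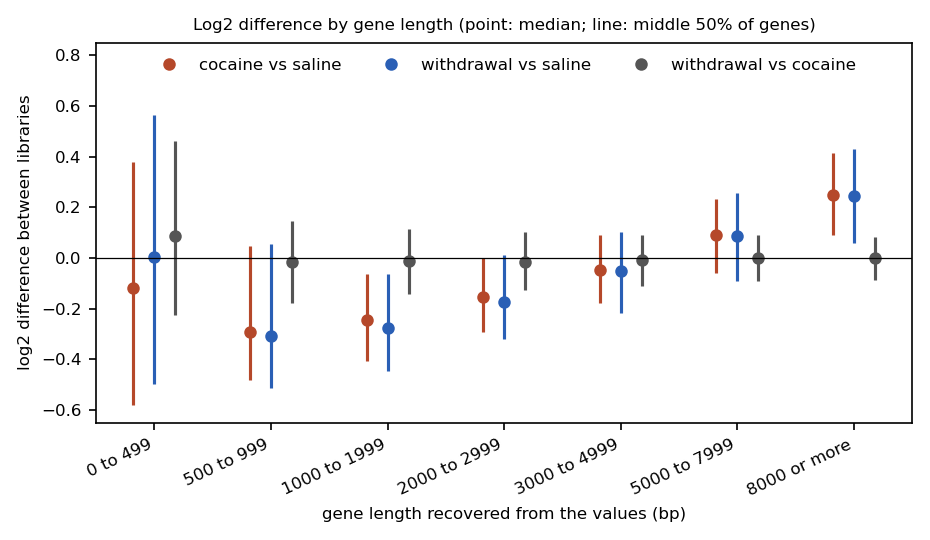
Median log2 difference between libraries (vertical axis) for tested genes grouped by length in bp (horizontal axis), in the 3 comparisons; points are medians over genes and lines span the middle 50% of genes. From genes of 500 up to 1000 bp to genes of 8000 bp or more medians rose from -0.29 to 0.25 for cocaine against saline. For withdrawal against saline they rose from -0.31 to 0.24, and for withdrawal against cocaine they lay between -0.015 and -0.0021. Genes under 500 bp lay above those of 500 up to 1000 bp, at -0.12, 0.0050 and 0.088 in these comparisons.

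The second comparison asked which transcripts differed from saline after 8 days of withdrawal. No saline group was kept for 8 days: the saline mice were killed 24 h after their last injection. Withdrawal therefore cannot be told apart from the longer time without injections. Slc17a7 fell to 3.96 ± 0.58 RPKM in the withdrawal library (-2.08 ± 0.12). Kcnq3 rose from 4.19 ± 0.58 to 17.9 ± 2.0 RPKM (1.98 ± 0.14), Tnr to 19.0 ± 0.51 RPKM (1.88 ± 0.092) and Bmpr2 to 15.2 ± 0.81 RPKM (1.86 ± 0.10). Igsf9b, a synaptic adhesion gene, rose by 1.90 ± 0.027, Grin2a by 1.82 ± 0.11 and Sv2c by 1.75 ± 0.066. Pxmp2, a peroxisomal membrane protein gene, fell by 1.60 ± 0.29, Hmgn5 by 1.48 ± 0.19, Ptpla by 1.34 ± 0.27 and Fxyd3 by 1.23 ± 0.31. In all, 557 genes were called higher and 473 lower, against a mean of 96.4 calls in simulated unchanged libraries, and lanes did not overlap for 44.2% of genes (10% by chance). The other genes among the largest changes were the uncertain models n-R5s185, Mir1892, Mir1893, A230065H16Rik, 4932418E24Rik and 4930500M09Rik.

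Medium spiny neuron dopamine and cAMP signalling genes had a median of 0.10, above all the random lists, with 3 higher, 0 lower and 27 without a call. Drd3, the D3 dopamine receptor, rose from 1.93 ± 0.80 to 5.77 ± 0.81 RPKM (1.41 ± 0.29) and Pde10a, a striatal phosphodiesterase, by 0.69 ± 0.031. Drd1a (-0.017 ± 0.083), Drd2 (0.083 ± 0.10) and Ppp1r1b (-0.39 ± 0.026) had no call. Neuropeptide and opioid system genes had a median of -0.44, below all the random lists, with 2 higher, 4 lower and 16 without a call. The list also lay below random lists matched on length (percentile 0.41), while length centring ended the outcome. Pmch fell by 2.02 ± 0.73, Cck, the cholecystokinin precursor, from 44.3 ± 7.2 to 20.7 ± 4.6 RPKM (-1.09 ± 0.22) and Avp, the vasopressin precursor, by 0.91 ± 0.20, and Oprm1 rose to 3.86 ± 0.65 RPKM (1.65 ± 0.24). Tac1 (-0.52 ± 0.051), Cartpt (-0.42 ± 0.082), Penk (-0.28 ± 0.033) and Pdyn (-0.035 ± 0.041) had no call. Peptide processing genes had a median of -0.26 and no call, within random lists matched on expression (percentile 9.2) and below those matched on length (percentile 1.9), with Pam at -0.35 ± 0.076. Ventral striatum genes (-0.11, Drd3 and Peg10 higher), dorsolateral striatum genes (-0.10, no call) and striatal interneuron genes (-0.15) lay within random lists. Among the interneuron genes Nos1 (0.80 ± 0.055) and Slc5a7 (0.66 ± 0.11) were higher and Calb2 (-0.77 ± 0.078) and Htr3a (-0.60 ± 0.27) lower. Length centring gave a median of -0.12 for neuropeptide genes (2 higher and 4 lower), 0.065 for ventral striatum genes (1 higher and 0 lower) and 0.023 for interneuron genes (1 higher and 0 lower). Under 75th percentile scaling the calls were 2 higher and 1 lower among interneuron genes. GC centring left 2 higher and 1 lower among interneuron genes. Calls that ended when a lane was dropped were those of Htr3a (-0.51 without saline replicate 3, -0.36 without withdrawal replicate 2). A dropped lane moved across a bound the peptide processing and secretory granule list (1.6 without withdrawal replicate 1), by percentile.

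Immediate-early and activity-regulated genes had a median of -0.31 (percentile 0.010), with 0 higher, 2 lower and 29 without a call. Nr4a1, a nuclear receptor gene, fell from 18.9 ± 1.1 to 9.19 ± 1.7 RPKM (-1.01 ± 0.15) and Gadd45b by 0.86 ± 0.25. Fos (-0.57 ± 0.34), Fosb (-0.52 ± 0.17), Arc (-0.45 ± 0.077) and Egr1 (-0.31 ± 0.062) had no call, and Bdnf, at 0.540 ± 0.17 RPKM, stayed below the filter. Glucocorticoid-responsive genes had a median of -0.34 (percentile 0.12), with 1 higher, 5 lower and 10 without a call. Sgk1, a kinase induced by glucocorticoids, fell from 17.5 ± 1.1 to 11.1 ± 1.9 RPKM (-0.64 ± 0.15) and Tsc22d3 by 0.65 ± 0.065, while Zbtb16 rose by 0.73 ± 0.066. Circadian clock genes had no call and lay within random lists, with a median of -0.027 that turned to 0.035 under scaling to the same 75th percentile and to 0.029 with the median difference set to 0. Chaperone genes had a median of -0.26 (percentile 2.5), with Hspe1 lower by -0.84 ± 0.12 and Hsp90aa1 by -0.61 ± 0.039; the list lay within random lists under the composite values, 75th percentile scaling, no filter, a pseudocount of 0.1 or GC centring. After centring by length the median came to -0.14 for immediate-early genes (0 higher and 1 lower), -0.22 for glucocorticoid genes (1 higher and 1 lower) and -0.15 for chaperone genes (0 higher and 0 lower). Calls under 75th percentile scaling were 1 higher and 0 lower among glucocorticoid genes and 0 higher and 1 lower among chaperone genes. GC centring left 0 higher and 1 lower among chaperone genes. With a lane dropped the call ended for Sgk1 (-0.52 without withdrawal replicate 3) and Hsp90aa1 (-0.58 without saline replicate 3, -0.58 without withdrawal replicate 1). A call was gained when 1 lane was left out for Fos (-0.67 without saline replicate 2, -0.81 without withdrawal replicate 1) and Fosb (-0.67 without saline replicate 1, -0.59 without withdrawal replicate 3). Percentiles that changed a list's outcome without 1 lane were those of the chaperone and heat shock list (5.9 without saline replicate 2, 8.2 without withdrawal replicate 2).

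Voltage-gated ion channel genes had a median of 0.24, above all the random lists, with 9 higher, 0 lower and 33 without a call, with Kcnq3 and Cacna1e (1.38 ± 0.037) among those higher. Axon guidance and adhesion genes (median 0.27) had 11 higher, 1 lower and 37 without a call, with Epha6 (0.94 ± 0.11) and Plxna1 (0.92 ± 0.059) among those higher, and glutamate receptor and postsynaptic density genes (median 0.23) had 4 higher, 0 lower and 39 without a call, with Grin2a among those higher. These 3 lists also lay above random lists matched on length. GABA system genes (median 0.057, no call) and chromatin regulator genes (median 0.13), with Mll2 (1.09 ± 0.044) and Hdac4 (0.93 ± 0.10) among 4 higher, lay above random lists matched on expression but within those matched on length (percentile 78.5 and percentile 83.4). Synaptic vesicle genes, with Sv2c, Pclo (0.64 ± 0.049) and Bsn (0.62 ± 0.035) higher, had a median of -0.046 (percentile 98.5) that turned to 0.027 under scaling to the same 75th percentile and to 0.0100 with the median difference set to 0 and to 0.0074 after GC centring, and lay within random lists matched on length (percentile 18.9). Length centring ended the outcomes of the GABA, chromatin and synaptic vesicle lists. Actin and dendritic spine genes lay within random lists (median -0.12), with Arhgap32 higher by 0.80 ± 0.028, Cdc42 lower by -0.63 ± 0.069 and Kalrn at 0.33 ± 0.034 without a call. Centred by length, the median was 0.11 for ion channel genes (6 higher and 0 lower), 0.13 for axon guidance genes (4 higher and 1 lower), 0.13 for glutamate genes (3 higher and 0 lower), 0.040 for chromatin genes (3 higher and 0 lower), -0.055 for synaptic vesicle genes (1 higher and 0 lower) and -0.053 for actin genes (0 higher and 0 lower). With 75th percentile scaling there were 8 higher and 0 lower among glutamate genes, 7 higher and 0 lower among chromatin genes and 2 higher and 0 lower among actin genes. GC centring left 8 higher and 0 lower among glutamate genes, 7 higher and 0 lower among chromatin genes and 2 higher and 0 lower among actin genes. The call ended without 1 lane for Cdc42 (-0.56 without withdrawal replicate 1). Also changed without 1 lane was the outcome (percentile) of the GABA synthesis, transport and receptor list (97.3 without saline replicate 3) and synaptic vesicle and release list (96.1 without withdrawal replicate 2).

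Cytosolic ribosomal protein genes had a median of -0.49 with 0 higher, 19 lower and 58 without a call, oxidative phosphorylation genes one of -0.41 with 0 higher, 10 lower and 65 without a call, and proteasome genes one of -0.43 with 0 higher, 3 lower and 28 without a call. These lists lay below all the random lists matched on expression, and the oxidative phosphorylation list within those matched on length (percentile 3.9). Rps23 fell to 69.7 ± 10.0 RPKM (-0.89 ± 0.12), Rpl36a by 0.79 ± 0.080, Ndufc1 by 0.78 ± 0.074, Atp5h by 0.76 ± 0.052 and Psma5 by 0.77 ± 0.11. When centred by length, 2 ribosomal and 1 oxidative phosphorylation calls were left, with medians of -0.26 and -0.21. When centred by length, the list median was -0.19 for proteasome genes (0 higher and 0 lower). Under 75th percentile scaling the calls were 0 higher and 10 lower among ribosomal protein genes and 0 higher and 1 lower among proteasome genes. GC centring left 0 higher and 10 lower among ribosomal protein genes and 0 higher and 1 lower among proteasome genes.

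Endothelial and mural genes had a median of 0.53, above all the random lists, with 9 higher, 0 lower and 16 without a call. Eng, Cdh5 and Pecam1, genes of the endothelial surface, rose by 0.83 ± 0.082, 0.82 ± 0.22 and 0.78 ± 0.20. Choroid plexus and ependymal genes had a median of -0.71 over 9 genes, below all the random lists. Over single pairs of lanes, however, this median ran from -0.68 to 0.033. Rarres2, chosen after its values were seen, was called lower (-0.71 ± 0.32), and Ttr differed by -0.95 ± 0.37 without a call. Oligodendrocyte precursor genes (0.31, percentile 99.5, Tnr higher) and meningeal genes (0.25, percentile 98.7, Fn1 higher by 1.11 ± 0.12) stood above random lists, and microglia and immune genes below (-0.22, percentile 1.4, no call). Length centring ended these 3 outcomes and turned the microglia median to 0.012. Against random lists matched on length, the precursor (percentile 97.53) and meningeal (percentile 98.8) lists stayed above, and the microglia list lay within (percentile 21.0). Cortical projection neuron genes lay within random lists (-0.19, percentile 7.8), with Slc17a7, Fezf2 (-0.74 ± 0.23) and Nrgn (-0.67 ± 0.046) lower. Within random lists were also myelin genes (-0.10, Enpp6 higher by 0.64 ± 0.20), astrocyte genes (-0.21, S100b lower by -0.67 ± 0.053), interferon-responsive genes (0.039, no call), septal and hypothalamic genes (0.062, Peg10 higher by 0.61 ± 0.018 and Zic2 lower by -0.74 ± 0.082), erythrocyte genes (-0.36, no call) and nuclear non-coding RNAs (-0.12, no call). Length centring gave a median of 0.13 for oligodendrocyte precursor genes (1 higher and 0 lower), 0.19 for meningeal genes (2 higher and 0 lower), 0.012 for microglia genes, -0.060 for cortical genes (0 higher and 1 lower) and 0.080 for septal genes (1 higher and 0 lower). Calls under 75th percentile scaling were 2 higher and 0 lower among meningeal genes and 2 higher and 1 lower among septal genes. GC centring left 14 higher and 0 lower among endothelial genes. Rarres2 (-0.46 without withdrawal replicate 3) and Fezf2 (-0.58 without withdrawal replicate 2) lost the call when 1 lane was left out. A single lane decided the call of Enpp6 (0.47 without saline replicate 3, 0.56 without withdrawal replicate 3). A call was gained when 1 lane was left out for Ttr (-1.27 without saline replicate 2, -1.14 without withdrawal replicate 1). The percentile crossed a bound without 1 lane for the meningeal and fibroblast list (97.1 without saline replicate 1) and microglia and immune list (7.8 without saline replicate 1, 2.7 without saline replicate 2, 6.0 without withdrawal replicate 1, 5.9 without withdrawal replicate 3). A dropped lane moved across a bound the septal, preoptic and hypothalamic neuron list (98.0 without saline replicate 1) and erythrocyte list (2.4 without withdrawal replicate 3), by percentile.

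Differences from saline followed gene length in the withdrawal library too. Genes called higher had a median length of 4572 bp and genes called lower 1519 bp, against 3531 bp for all tested genes, and the Spearman correlation across genes of the difference with length was 0.422, where genes are not independent replicates. The split of 557 higher and 473 lower genes became 729 and 309 with the median difference set to 0, 765 and 280 with lanes scaled to the same 75th percentile, 595 and 175 when centred by length, and 731 and 303 when centred by GC content, with which the differences correlated at 0.0712. Of the 32 lists, 9 lay below and 10 above random lists. Centring by length turned the sign of the myelin (0.033), nuclear non-coding RNA (0.028), interneuron (0.023) and ventral striatum (0.065) medians. Centring within bins of gene length, an alternative chosen after seeing the data, brought Pde10a (0.41), Peg10 (0.51), Nos1 (0.52), Calb2 (-0.51), Htr3a (-0.40), Gadd45b (-0.55), Tsc22d3 (-0.57), Hspe1 (-0.53), Hsp90aa1 (-0.54), Pclo (0.36), Bsn (0.34), Arhgap32 (0.52), Cdc42 (-0.51), Rpl36a (-0.46), Ndufc1 (-0.47), Atp5h (-0.45), Psma5 (-0.46), Rarres2 (-0.54), Fezf2 (-0.54), Nrgn (-0.36), S100b (-0.42) and Zic2 (-0.57) under 1.5 times. It left Mir1892 (-1.14) past 1.5 times, but with lanes that overlapped, which ended the call too. A pseudocount of 1 ended the calls of Slc5a7 (0.58), Htr3a (-0.48), Fezf2 (-0.56) and Enpp6 (0.54). GC centring, also chosen after seeing the data, ended the calls of Htr3a (-0.55), Hsp90aa1 (-0.51), Cdc42 (-0.54) and Rarres2 (-0.67, past 1.5 times with lanes that overlapped). The composite value per library ended the calls of Htr3a (-0.56). Scaling to the same 75th percentile ended the calls of Htr3a (-0.55), Sgk1 (-0.57), Tsc22d3 (-0.58), Hsp90aa1 (-0.53), Cdc42 (-0.55) and Rarres2 (-0.64, past 1.5 times with lanes that overlapped). Setting the median difference to 0 ended the calls of Htr3a (-0.55), Hsp90aa1 (-0.55), Cdc42 (-0.57) and Rarres2 (-0.66, past 1.5 times with lanes that overlapped). With 75th percentile scaling the list median was 0.17 for medium spiny neuron genes, 0.13 for GABA genes, -0.19 for chaperone genes (percentile 2.6, within the bounds) and 0.20 for chromatin genes. With the median difference set to 0 the list median was 0.15 for medium spiny neuron genes and 0.11 for GABA genes. With GC centring the list median was 0.050 for clock genes, 0.17 for medium spiny neuron genes, 0.11 for GABA genes and -0.21 for chaperone genes (percentile 2.7, within the bounds). Likewise with GC centring the list median was 0.20 for chromatin genes. With the composite values the list median was 0.036 for GABA genes and -0.25 for chaperone genes (percentile 3.4, within the bounds). With a filter of 5 RPKM the list median was 0.031 for dorsolateral striatum genes, 0.012 for nuclear non-coding RNA genes (percentile 98.2, outside the bounds), 0.11 for meningeal genes (percentile 90.6, within the bounds) and -0.31 for choroid plexus genes (percentile 8.3, within the bounds). Likewise with a filter of 5 RPKM the list median was -0.28 for interferon genes. With no filter the list median was -0.26 for chaperone genes (percentile 2.8, within the bounds), -0.19 for microglia genes (percentile 3.4, within the bounds), 0.17 for meningeal genes and -0.24 for choroid plexus genes. Likewise with no filter the list median was -0.36 for erythrocyte genes (percentile 2.0, outside the bounds). With a pseudocount of 0.1 the list median was -0.27 for chaperone genes (percentile 2.9, within the bounds).

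The cocaine and withdrawal libraries were set against the same saline library, which by itself makes their differences alike. Across 14051 genes the log2 differences from saline correlated with a Pearson r of 0.80 and a Spearman rho of 0.80, where simulated unchanged libraries gave a mean r of 0.50 and at most 0.55, and genes are not independent replicates. The covariance was 0.102 against 0.0209 simulated, a difference of 0.0808. Of the called genes, 318 were higher in both, such as Tnr, Bmpr2 and Grin2a, where 16.3 were expected for independent lists and 9.08 in the simulation. Another 125 were lower in both, such as Slc17a7, Pmch and Rps23, where 11.4 and 8.53 were expected. There were 2 opposite calls. Split into independent deviations of the 3 libraries, the variance of the differences came to 0.102 for saline, 0.0126 for cocaine and 0.0397 for withdrawal. The saline value equals the covariance above by construction, so any effect shared by both cocaine-exposed libraries is counted in it. The saline lanes also stood apart in the sum of RPKM over genes, 403628 to 409218 against 358568 to 365437 in the other 6 lanes, and in the ratio of reads summed over genes to the lane total, 1.30 to 1.31 against 1.26 to 1.27. The simulated libraries hold only the spread between lanes, and the saline control was 1 library and could not be split, so part or all of the excess may come from the shared control.

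The third comparison asked how withdrawal differed from the end of cocaine treatment. Here too the time since the last injection differed between the groups. The haemoglobin genes Hbb-b1 and Hba-a2 fell from 159 ± 12 to 85.7 ± 4.4 RPKM (-0.89 ± 0.073) and from 197 ± 20 to 115 ± 4.5 RPKM (-0.77 ± 0.092), and Hbb-b2 by 0.90 ± 0.11. These near-identical globin copies are uncertain as single genes. Sgk1 fell from 20.7 ± 0.64 to 11.1 ± 1.9 RPKM (-0.88 ± 0.14) and Mgp, matrix Gla protein, from 12.0 ± 3.2 to 4.97 ± 2.8 RPKM (-1.28 ± 0.47). S100a11 and Ndufaf1 fell by 1.13 ± 0.24 and 0.89 ± 0.25, and Zfp809, a zinc finger gene, rose by 0.77 ± 0.22. Ttr fell from 7.51 ± 2.4 to 0.949 ± 0.36 RPKM (-2.45 ± 0.32). The other large changes, in Mir1249, Snord82, Mir24-1, Mir3074-1, Scarna6, Snord100, Mir369 and Rn4.5s, rested on short or repeated models and are uncertain. In all, 66 genes were called higher and 77 lower, 143 against a mean of 96.4 and at most 121 in simulated unchanged libraries. A single call of this comparison may thus come from the spread between lanes alone. The limma test over lanes gave 26 higher and 26 lower genes. Lanes did not overlap for 18.1% of genes (10% by chance). Leaving out 1 lane eases the lane condition, and the number higher was then 122 without cocaine replicate 1, 135 without cocaine replicate 3, 104 without withdrawal replicate 1, 126 without withdrawal replicate 2, 119 without withdrawal replicate 3, and the number lower 120 without cocaine replicate 1, 145 without cocaine replicate 2, 122 without cocaine replicate 3, 129 without withdrawal replicate 1, 146 without withdrawal replicate 2, 154 without withdrawal replicate 3.

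Medium spiny neuron dopamine and cAMP signalling genes had a median of 0.17, above all the random lists, with 26 of 30 members positive. Drd3 rose from 3.32 ± 0.99 to 5.77 ± 0.81 RPKM (0.74 ± 0.25) and was their single call, while Drd2 (0.41 ± 0.15), Ppp1r1b (0.36 ± 0.037) and Drd1a (0.11 ± 0.023) had none. Ventral striatum genes lay within random lists (0.040), with Stard5 (0.76 ± 0.049) and Drd3 higher. Glucocorticoid-responsive genes had a median of -0.13 (percentile 0.18), with Sgk1 and Plin4 (-0.69 ± 0.16) lower. Chaperone genes (-0.11, percentile 0.010) and cortical projection neuron genes (-0.18, percentile 0.11) stood below random lists without a call. Erythrocyte genes had a median of -0.74 over 7 genes, below all the random lists, with 5 lower, among them Alas2 (-0.74 ± 0.30). Septal and hypothalamic genes (-0.092, percentile 1.5, Slc17a6 lower by -0.59 ± 0.14) and choroid plexus genes (-0.22, percentile 1.1, Ttr the single call) stood below, and interferon-responsive genes above (0.17, percentile 98.9), where Ifit3, a gene with a close copy and so uncertain, was lower (-0.72 ± 0.34); at a filter of 5 RPKM these 3 outcomes ended, with the choroid median at 0.020 and the interferon median at -0.10, while the meningeal (-0.20, percentile 0.35) and proteasome (-0.055, percentile 2.3) lists came to lie below random lists and the ion channel list (0.054, percentile 99.1) above. Without 1 of the lanes the call was lost for Drd3 (0.52 without cocaine replicate 1) and Plin4 (-0.56 without cocaine replicate 3). Calls that ended when a lane was dropped were those of Alas2 (-0.50 without withdrawal replicate 3) and Slc17a6 (-0.50 without cocaine replicate 3, -0.48 without withdrawal replicate 1). With a lane dropped the call ended for Ifit3 (-0.56 without cocaine replicate 2, -0.45 without withdrawal replicate 2). Percentiles that changed a list's outcome without 1 lane were those of the septal, preoptic and hypothalamic neuron list (4.6 without cocaine replicate 1, 6.7 without cocaine replicate 3, 3.7 without withdrawal replicate 2) and choroid plexus and ependymal list (5.2 without cocaine replicate 1, 2.9 without withdrawal replicate 2, 5.3 without withdrawal replicate 3). Also changed without 1 lane was the outcome (percentile) of the interferon-responsive and inflammatory list (49.1 without cocaine replicate 2, 33.5 without cocaine replicate 3, 94.8 without withdrawal replicate 1, 82.6 without withdrawal replicate 3).

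The other lists lay within random lists matched on expression. Immediate-early genes had a median of 0.0016 without a call, with Fos at 0.14 ± 0.34, Fosb at -0.23 ± 0.11, Arc at 0.24 ± 0.11 and Egr1 at 0.0016 ± 0.10, and Bdnf below the filter. Neuropeptide genes had a median of 0.011, with Pomc higher by 0.83 ± 0.34, and Penk (0.12 ± 0.044), Pdyn (0.26 ± 0.048), Tac1 (0.23 ± 0.071) and Cartpt (0.29 ± 0.069) without a call. Endothelial genes (0.069, Esam higher by 0.62 ± 0.17) lay above random lists matched on length, and synaptic vesicle genes (-0.049, no call) below (percentile 2.0). Meningeal genes (0.038) had Bgn higher (0.65 ± 0.21) and Mgp lower, axon guidance genes (0.011) had Ntng1 lower (-0.60 ± 0.15), and circadian clock genes (-0.044) had Gm129 lower (-0.59 ± 0.12). No call was made among ribosomal protein (-0.0065, positive with the median difference set to 0), oxidative phosphorylation (-0.011), proteasome (-0.055), ion channel (0.042), glutamate receptor (0.022), GABA (-0.013), chromatin (0.041), actin (0.020) and peptide processing genes (-0.068), where Kalrn was at 0.056 ± 0.050 and Pam at -0.24 ± 0.063. Nor was one made among myelin (-0.056), oligodendrocyte precursor (-0.047), astrocyte (-0.040), microglia (-0.052), interneuron (-0.034), dorsolateral striatum (-0.083) and nuclear non-coding RNA genes (0.050). The call ended without 1 lane for Pomc (0.50 without cocaine replicate 2) and Esam (0.45 without withdrawal replicate 2). Bgn (0.52 without cocaine replicate 2, 0.54 without withdrawal replicate 3) and Ntng1 (-0.49 without cocaine replicate 3, -0.52 without withdrawal replicate 1) lost the call when 1 lane was left out. A single lane decided the call of Gm129 (-0.57 without cocaine replicate 1, -0.48 without withdrawal replicate 1). The percentile crossed a bound without 1 lane for the immediate-early and activity-regulated list (0.93 without withdrawal replicate 1) and endothelial and mural cell list (97.9 without cocaine replicate 1). A dropped lane moved across a bound the meningeal and fibroblast list (97.9 without cocaine replicate 3, 97.7 without withdrawal replicate 3) and proteasome subunit list (0.57 without cocaine replicate 1, 0.13 without withdrawal replicate 2), by percentile. Percentiles that changed a list's outcome without 1 lane were those of the voltage-gated ion channel list (99.5 without cocaine replicate 1, 98.5 without withdrawal replicate 2) and chromatin and DNA methylation regulator list (99.1 without cocaine replicate 2, 99.3 without cocaine replicate 3, 99.9 without withdrawal replicate 1). Also changed without 1 lane was the outcome (percentile) of the peptide processing and secretory granule list (0.98 without cocaine replicate 1, 0.90 without cocaine replicate 2, 2.2 without withdrawal replicate 1) and oligodendrocyte and myelin list (1.6 without withdrawal replicate 3). The percentile crossed a bound without 1 lane for the astrocyte list (1.8 without withdrawal replicate 1) and small nucleolar RNA hosts and nuclear long non-coding RNAs (RNA fraction and quality) list (98.7 without cocaine replicate 2, 97.6 without cocaine replicate 3).

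The differences between withdrawal and cocaine did not follow gene length (Spearman correlation 0.0128 across genes), and the split became 69 higher and 73 lower when centred by length. They did follow GC content, with a Spearman correlation of 0.294 across genes. Centring within bins of GC content, chosen after seeing the data, gave 62 higher and 67 lower genes, of which 56 and 58 had been called before. With it the septal list came to lie within random lists, the astrocyte (-0.070, percentile 0.81), microglia (-0.089, percentile 0.48) and peptide processing (-0.091, percentile 0.35) lists below them, and the glutamate receptor (0.038, percentile 98.0), nuclear non-coding RNA (0.084, percentile 99.6) and ventral striatum (0.076, percentile 99.3) lists above. Of the 32 lists, 6 lay below and 2 above random lists, the latter being 5 after GC centring, 4 without cocaine replicate 1 and 4 without cocaine replicate 3. Centring within bins of gene length, an alternative chosen after seeing the data, brought Slc17a6 (-0.57) under 1.5 times. GC centring, also chosen after seeing the data, ended the calls of Slc17a6 (-0.51) and Ntng1 (-0.57). The composite value per library ended the calls of Slc17a6 (-0.58) and Gm129 (-0.57). Scaling to the same 75th percentile ended the calls of Slc17a6 (-0.58). Setting the median difference to 0 ended the calls of Slc17a6 (-0.58). A pseudocount of 1 ended the calls of Slc17a6 (-0.55), Esam (0.57), Ntng1 (-0.56) and Gm129 (-0.57). With GC centring the list median was -0.035 for immediate-early genes, -0.018 for neuropeptide genes and 0.0004 for GABA genes. With length centring the list median was 0.050 for ion channel genes (percentile 97.52, outside the bounds). With the composite values the list median was -0.080 for peptide processing genes (percentile 1.4, outside the bounds), -0.020 for immediate-early genes and 0.078 for endothelial genes (percentile 97.6, outside the bounds). With a filter of 5 RPKM the list median was -0.0096 for immediate-early genes and -0.0047 for neuropeptide genes. With no filter the list median was -0.0096 for immediate-early genes, -0.0047 for neuropeptide genes, 0.042 for ion channel genes (percentile 97.55, outside the bounds) and -0.055 for proteasome genes (percentile 2.4, outside the bounds). Likewise with no filter the list median was -0.12 for choroid plexus genes (percentile 4.7, within the bounds) and 0.069 for interferon genes (percentile 89.6, within the bounds).

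**Figure D2:**
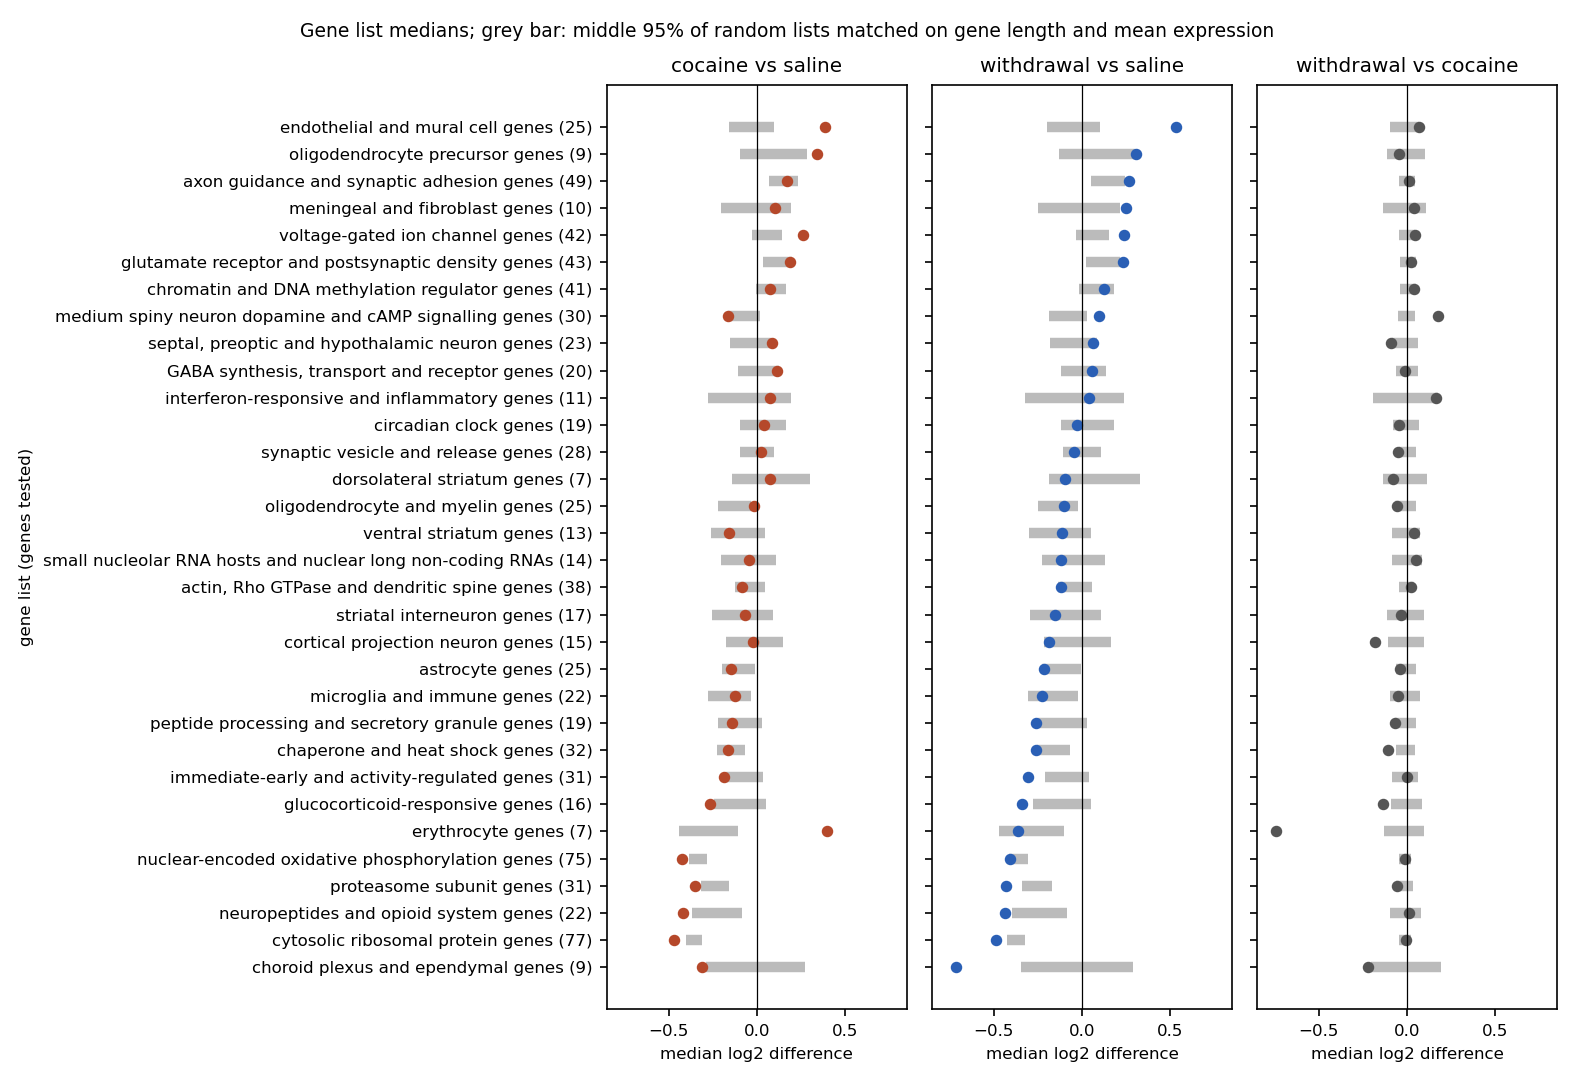
Median log2 difference of the 32 gene lists (horizontal axis) in the 3 comparisons, with the middle 95% of random lists matched on length and expression as grey bars and the number of tested genes in brackets. Ribosomal protein genes lay at -0.47 and -0.49 against saline and at -0.0065 between withdrawal and cocaine, where setting the median difference to 0 turned the sign, and medium spiny neuron genes at -0.17, 0.098 and 0.17.

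**Figure D3:**
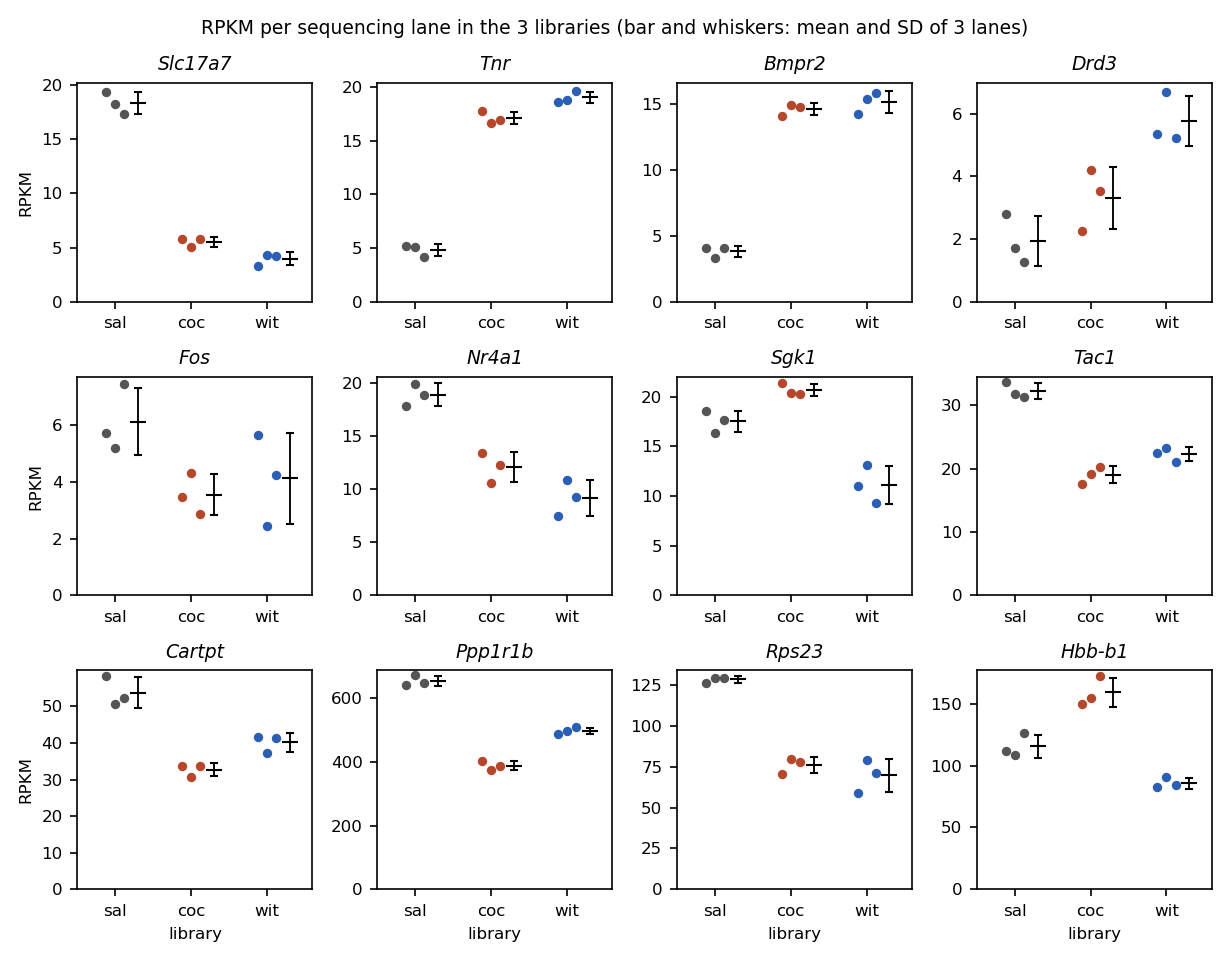
RPKM (vertical axis, from 0) of 12 named genes in each lane (points) of the saline (sal), cocaine (coc) and withdrawal (wit) libraries, with the mean and SD of the 3 lanes as bar and whiskers. Slc17a7 had means of 18.3, 5.54 and 3.96 RPKM in saline, cocaine and withdrawal, and the lanes are technical runs of 1 library.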

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

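Centring within bins of gene length, centring within bins of GC content and leaving out gene models under 200 bp were chosen after the results were seen; all other alternatives were planned. Counts are given as higher and then lower. A size limit of 25% gave 1374 and 1703 for cocaine against saline, 1563 and 2134 for withdrawal against saline, 313 and 340 for withdrawal against cocaine. A limit of 2 times gave 112 and 34 for cocaine against saline, 146 and 44 for withdrawal against saline, 17 and 10 for withdrawal against cocaine. A filter of 5 RPKM gave 182 and 217 for cocaine against saline, 266 and 325 for withdrawal against saline, 15 and 28 for withdrawal against cocaine. No filter gave 513 and 451 for cocaine against saline, 674 and 614 for withdrawal against saline, 138 and 158 for withdrawal against cocaine. Dropping the condition on the lanes gave 503 and 450 for cocaine against saline, 679 and 625 for withdrawal against saline, 155 and 159 for withdrawal against cocaine. The composite values without that condition gave 495 and 425 for cocaine against saline, 667 and 580 for withdrawal against saline, 141 and 141 for withdrawal against cocaine. limma over lanes without a size limit gave 1429 and 2018 for cocaine against saline, 1688 and 2551 for withdrawal against saline, 26 and 26 for withdrawal against cocaine. Scaling to the same 75th percentile gave 535 and 204 for cocaine against saline, 765 and 280 for withdrawal against saline, 67 and 76 for withdrawal against cocaine. Setting the median difference to 0 gave 505 and 230 for cocaine against saline, 729 and 309 for withdrawal against saline, 69 and 74 for withdrawal against cocaine. Length centring gave 477 and 98 for cocaine against saline, 595 and 175 for withdrawal against saline, 69 and 73 for withdrawal against cocaine. GC centring gave 496 and 237 for cocaine against saline, 731 and 303 for withdrawal against saline, 62 and 67 for withdrawal against cocaine. A pseudocount of 0.1 gave 526 and 409 for cocaine against saline, 678 and 578 for withdrawal against saline, 94 and 112 for withdrawal against cocaine. A pseudocount of 1 gave 334 and 264 for cocaine against saline, 445 and 362 for withdrawal against saline, 49 and 53 for withdrawal against cocaine. Without models under 200 bp there were 402 and 326 for cocaine against saline, 542 and 464 for withdrawal against saline, 56 and 72 for withdrawal against cocaine. These settings change the size limit, the genes tested or the conditions by construction, except the pseudocounts, scalings and both centrings, for which the cause was not tested. Of the genes called at first, length centring kept 293 higher and 77 lower for cocaine against saline, 394 higher and 133 lower for withdrawal against saline, 65 higher and 69 lower for withdrawal against cocaine. With each lane left out in turn, withdrawal against cocaine gave 89 to 135 higher and 120 to 154 lower genes, since fewer lanes must not overlap, and the counts against saline stayed within 1.5 times. The limma counts for withdrawal against cocaine fell to 4 to 21 higher and 7 to 21 lower genes with 1 lane left out, where fewer lanes enter the fit. At a filter of 5 RPKM limma gave 41 lower genes for withdrawal against cocaine, and with 75th percentile scaling 1321 lower genes for cocaine against saline; the cause was not tested. With the lane number as a replicate block limma gave 1318 and 1971 for cocaine against saline, 1579 and 2542 for withdrawal against saline, 18 and 21 for withdrawal against cocaine, each within 1.5 times of the fit without the block. The numbers did not pair the lanes: the 9 correlations between same-numbered lanes ran from -0.051 to 0.076, and 2 of 9 lanes correlated best with their own number. The correlation r of the differences from saline was 0.864 at a filter of 5 RPKM, 0.735 without a filter, 0.767 with a pseudocount of 0.1, 0.816 with a pseudocount of 1 and 0.759 to 0.821 with a lane left out. It was judged against an SD of 0.031 over 27 choices of 1 lane per library, a measure set after values were seen. Of the 32 lists, cocaine against saline had 6 above random lists when these were matched on length and 4 below after length centring, withdrawal against saline 5 above after length centring, and withdrawal against cocaine 2 to 4 above with a lane left out and 5 above after GC centring. Medians changed sign for choroid plexus genes in withdrawal against cocaine at 5 RPKM (0.020), and for interferon-responsive genes at 5 RPKM (-0.10) and with a lane left out (-0.043 to 0.20). Length centring turned the chromatin (-0.020) and synaptic vesicle (-0.031) medians of cocaine against saline and the microglia median of withdrawal against saline (0.012). The synaptic vesicle median of withdrawal against saline turned with 75th percentile scaling (0.027), with the median set to 0 (0.0100) and with GC centring (0.0074); the cause was not tested. Of 96 list outcomes, 25 changed with a lane left out and 28 under other planned settings, and of 297 results of single named genes 68 and 48 did; length centring ended 65 calls of named genes, and 0 reversed under any setting. Count tests (edgeR and DESeq2) were planned for whole reads and were not run, since reads were fractional. Depth limits low genes most, since 1 read in a gene of 2 kb is worth up to 0.0902 RPKM.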

Other observations

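The gene families in this paragraph, centring by gene length, and the tests of a deviating saline library, blood, vessel tissue, GC content of globin genes and cortical tissue were chosen after the results were seen. Families were formed from gene symbols (98 families with at least 12 tested members) and set against random lists matched on length and expression. With members drawn at random, 4.9 would lie outside the middle 95%. For cocaine against saline 10 lay below and 9 above. The numbers were 11 and 11 for withdrawal against saline, and 3 and 5 for withdrawal against cocaine. Lanes were not left out for these families. The 48 genes named Mrpl, of the large mitochondrial ribosomal subunit with a pseudogene, had a median of -0.35 in the cocaine library (percentile 0.060, 6 lower and none higher) and -0.34 in the withdrawal library (percentile 0.48, 2 lower). The 56 genes named Eif, translation initiation factors with their kinases and binding proteins and argonaute genes, had medians of -0.20 and -0.27 (percentile 0.040 and percentile 0.010), with 2 higher and 2 lower and then 2 higher and 3 lower; Eif2c2, an argonaute gene, rose by 1.26 ± 0.076 and 1.39 ± 0.023. The 24 kinesin genes had medians of 0.23 and 0.26 (percentile 99.2 and percentile 99.4), with 2 and 3 higher and none lower, among them Kif26b by 1.21 ± 0.12 in the withdrawal library. Also outside in both comparisons with saline were Cacna, Gpr, Klhl, Mir, Sema and Slc above and Pcdhga, Psmd, Rpl and Rps below. Most members of Rpl (43 of 47), Rps (30 of 43), Psmd (11 of 14) and Cacna (8 of 12) were in the fixed gene lists. These families therefore largely repeat the outcomes of those lists. Between withdrawal and cocaine the 8 families were below Arl (-0.11, percentile 0.63), Pcdha (-0.35, percentile 0) and Ube (-0.056, percentile 2.2), and above Col (0.18, percentile 100), Mir (0.20, percentile 99.99), Myo (0.078, percentile 97.7), Ptpn (0.10, percentile 98.5) and Snora (0.60, percentile 100). Snora and Mir models are very short, and Pcdha models share exons, as do Pcdhga models. Outcomes of these families are therefore uncertain in every comparison. Col holds Col4a3bp, which is no collagen.

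Ribosomal protein and oxidative phosphorylation genes were lower than in saline in both other libraries; after centring within bins of gene length the ribosomal medians went from -0.47 to -0.24 (lane pairs -0.30 to -0.19) and from -0.49 to -0.26, the oxidative phosphorylation medians to -0.20 (lane pairs -0.22 to -0.15) and -0.21, from -0.42 and -0.41, all 4 below the random lists, which argues against length as the whole cause. Against this, the medians shrank by about as much as they kept, the calls left were 0 and 2 ribosomal and 2 and 1 oxidative phosphorylation genes because differences then fell under 1.5 times, and uncentred the oxidative phosphorylation list of withdrawal lay within lists matched on length (percentile 3.9). GC content is argued against likewise, the median nearest to 0 after centring being -0.37. A deviation of the saline library alone cannot be told apart from an effect of cocaine that lasted into withdrawal, the biological explanation, which stays open and untested, since either gives lists that hardly differ between withdrawal and cocaine (the larger of the medians -0.011). The saline library stood apart over the 14051 genes (variance 0.102, against 0.0126 for cocaine and 0.0397 for withdrawal) and in its RPKM sums (403628 to 409218 per lane against 358568 to 365437), which either explanation allows.

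Haemoglobin genes were lower in the withdrawal than in the cocaine library. Alas2, an erythroid gene with sequence of its own, differed by -0.74, beside -0.75 for alpha and -0.90 for beta globin, so a different amount of blood left in the tissue is a candidate explanation, although the Alas2 call ended without withdrawal replicate 3 (-0.50). Less vessel tissue in the withdrawal library is argued against by the endothelial and mural list, whose median was 0.069 (SD over lane pairs 0.043). A trend with GC content is argued against: after GC centring the alpha globin genes were at -0.79 or below, and for the beta globin genes, for which the reference gave no GC content, taking away the lowest median of any GC bin (-0.11) left -0.77 or below. Against saline, erythrocyte genes had a median of 0.40 in the cocaine library, above all the random lists. In the withdrawal library it was -0.36, within random lists and without a call. Length centring gave 0.66 with 5 higher for cocaine and -0.12 without a call for withdrawal. The difference may thus lie in a high cocaine library, a low withdrawal library or both. An effect of withdrawal on blood cells stays open, untested.

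Slc17a7 was lower in both libraries than in saline, and a larger share of cortical tissue in the saline library might give this. Of 18 other cortical genes 5.56% (1 gene) were lower by 1.5 times in both comparisons, which met the bound of 25% written to speak against cortical tissue; but a condition of at least 10 such genes at 3 RPKM in saline was added after this value was seen, and 8 reached it, so the test is read as undecided and the explanation cannot be told apart from others. Chosen after their values were seen, Neurod2 went from 0.899 ± 0.085 RPKM in saline to 0.324 ± 0.20 and 0.275 ± 0.040 RPKM and Nrgn from 160 ± 6.9 to 124 ± 7.0 and 100 ± 3.5 RPKM, while Cux2 went from 6.79 ± 0.51 to 9.40 ± 0.49 and 9.69 ± 0.61 RPKM. The test's log2(RPKM + 0.5) scale understates changes of low genes. Neurod6, chosen with values seen, differed by only -0.50 and -0.55 (0.452, 0.174 and 0.158 RPKM). Fezf2 (-0.30 and -0.74), Rtn4rl2 (-0.74 and -0.52), Neurod1, Emx2, Lhx2 and 6330527O06Rik fell in both comparisons. Only Cux2, Rasgrf2 (0.47 and 0.24) and Nptx1 (0.17 and 0.020) rose in both. Gene length is argued against, since Slc17a7 stayed at -1.54 or below after length centring, and an effect of cocaine stays open, untested.

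limma over lanes gave 3447 genes for cocaine against saline, 4239 for withdrawal against saline and 52 for withdrawal against cocaine. In each comparison 1 of the 10 splits of the 6 lanes, the real one, reached its count, and the highest other splits gave 2, 1 and 2 genes. With 10 splits no share under 0.05 is possible, and the lanes of a library are not independent samples.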
